A study of Mus musculus with 2 samples.

How the data were processed

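Chromatin immunoprecipitation with an antibody against H3K27me3 was followed by sequencing of fragments of 300 to 500 bp, per the labels, from hearts of newborn mice of the strain B6NTac;B6NCrl/Lap. The labels give 1 group with 2 biological replicates, the first sequenced as 2 technical replicates and the second as 1, and both are pools of male and female animals. The labels call them biological replicates, so the spread between them covers pools of animals as well as library making. It does not measure the spread between single animals. Replicate numbers were taken from the labels.

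The authors deposited peak lists in mm10 coordinates, and per the notes deposited with the samples the format is narrowPeak. Per those deposited notes, each replicate's peaks derive from its own alignments and 1 control file, the pooled peaks from both replicates' alignments and 2 control files, and the replicated peaks from the pooled list and both replicates' lists. The peak caller, its version, its limits, the aligner and the rule by which a peak counted as replicated are not given in the sources used here. Each deposited peak carries a signal value, the authors' enrichment of the peak, here between 1.34 and 14.1 in the replicated list. It also carries −log10 p and −log10 q values as deposited, with a lowest −log10 p of 2.01 in the replicated list. Signal and −log10 values are the authors' own for each peak and served to describe, rank or filter peaks within a list, and between the replicates only for the correlation and the ratio of signal values at overlapping peaks. They depend on depth and on the control of each call, so a longer list may reflect depth, which is unknown here, and numbers of peaks are not numbers of marked sites.

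Genes came from the GENCODE vM21 annotation of the mouse assembly GRCm38, the same build as mm10, and every deposited peak lay within its chromosome lengths. Peaks lay on 20 chromosomes (the autosomes and X), and 21728 protein-coding gene symbols of these were used. A gene was called marked when a peak covered at least 1 bp of the window from 2 kb before to 2 kb after the TSS of any annotated transcript. Covered length was the largest number of base pairs under merged peaks within 5 kb of a TSS, in windows of 10001 bp. No length can exceed the window, so a small SD at a gene covered almost throughout says little about precision. Values with SD are means of the lengths from each replicate's own peaks. Lengths with neither an SD nor a named replicate are from the replicated list. These are different measures, and genes given in one should not be ranked against genes given in the other. A neighbouring gene's peak can mark a promoter, so overlapping or closely spaced genes are not independent.

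Gene lists (23, with 754 entries) and families defined by symbol patterns (30) were tested with Fisher's exact test, two-sided, against all other protein-coding genes. The Benjamini-Hochberg adjustment ran over the 23 lists and over the 30 families separately, with a threshold of 0.05, so adjusted values are adjusted over the lists alone. Of the list entries 751 matched a symbol, 1 matched through an older symbol, and 2 are not protein-coding genes in the annotation and were left out. Shares have Wilson intervals at 95%, and a count of 0 is given with the share that 3 counts would make. Lists, families, windows, tests, the naming rule and the alternative settings were fixed before the data were examined. The rule named, for each list, the 3 marked members with most covered sequence and the first unmarked member (the first 4 where none was marked), all marked cardiac transcription factors, the genes with the 10 largest covered lengths over the gene body with 5 kb on either side, the genes of the 5 largest domains, and Cdkn2a, Cdkn2b, Myh6, Myh7, Nppa, Nppb, Tnni1 and Tnni3.

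Replicates were compared by the share of peaks that overlap by at least 1 bp and by the Jaccard index of base pairs, against 100 circular shifts within chromosomes (seed 1). Base pairs were assigned to promoters first, then exons, introns and intergenic sequence, all by protein-coding genes, so intergenic sequence includes non-coding genes. Domains are replicated peaks joined across gaps of up to 3 kb and ranked by base pairs under peaks. Alternatives were windows of 1 and 5 kb, the pooled list, each replicate's own list, replicated peaks with −log10 q of at least 2, the stronger part of the replicated peaks by signal value (at or above the median), 25% of a window covered, the 5′-most TSS, a background matched in GC content (10 genes per member), other joining distances, and stricter overlap. A further setting, leaving out the X chromosome, was added after the data were seen.

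On simulated peaks, 1000 planted promoter peaks marked their 1000 genes and 0 others of 21728. Of 1000 random collections of 23 lists of 30 genes, 5.8% gave a false call. Genes were marked independently there, so this rate does not cover lists of neighbours that share peaks, such as the Hox genes. A list of 30 genes with 50% marked, against 19.1% elsewhere, was called in 81.0% of runs, and with 40% marked in 42.0%, so a moderate excess in a short list can be missed. Sets of 20000 peaks planted with 50% in common gave an overlap of 50.3%, and 0.595% after a shift. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Reads, alignments and signal tracks were not analysed here, and the Y and mitochondrial chromosomes held no peaks in any of the 4 lists.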

Results

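Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark that Polycomb repressive complexes place on silenced genes, was mapped by chromatin immunoprecipitation and sequencing in hearts of newborn mice (postnatal day 0). The series held 1 group with 2 biological replicates, the hearts of 15 mice for replicate 1 and pooled hearts for replicate 2, each from both sexes. It held no second tissue, age or antibody, so the data address where the mark lay and how far the replicates shared it. Hearts hold several cell types, so a peak at a gene may come from only some of the cells. The peak lists do not show whether a gene is silenced in the cells that express it. The authors deposited 4 peak lists in mm10 coordinates. The replicated list held 27859 peaks over 28.5 Mb, or 1.11% of the genome, with a median width of 581 bp. The pooled list held 91947 peaks, replicate 1 alone 66315 and replicate 2 alone 71312. Read depth is unknown, because peak lists carry no read totals. Intervals given for shares therefore cover the counting of genes only, and tests across genes describe these peak lists, since genes are not replicates.

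Genes that specify other body regions and other tissues mostly carried the mark. All 39 Hox genes, the regulators of position along the body axis, had a replicated peak within 2 kb of a transcription start site (TSS), as did 68 of 69 transcription factors of the nervous system, the exception being Neurod4. The mark also lay on 38 of 43 skeletal muscle and mesoderm factors, 25 of 30 endoderm and gut factors and 51 of 54 secreted developmental signals. Across all 21728 protein-coding genes, 4113 promoters (18.9%) were marked. Each of these lists stood above the other genes by Fisher's exact test, two-sided, with adjusted p = 4.26e-28 for Hox genes, 5.77e-47 for neural factors, 5.96e-22 for muscle and mesoderm factors, 1.38e-13 for endoderm factors and 1.64e-32 for signals.

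The marked developmental genes were covered over long stretches. In the 10001 bp around a TSS, the median length under replicated peaks was 9.91 kb for Hox genes, 9.72 kb for neural factors, 9.54 kb for muscle and mesoderm factors and 8.82 kb for endoderm factors. Cdx2, a regulator of the intestine (chromosome 5, 147300805 to 147307270), was covered over 9.81 ± 0.196 kb in the replicates' own peaks (SD, n = 2), and Foxa2, a factor of the foregut and liver, over 9.35 ± 0.177 kb (SD, n = 2). Emx2, a forebrain regulator on chromosome 19, was covered over 9.40 ± 0.330 kb (SD, n = 2). Among the signals, Wnt7b was covered over 9.62 ± 0.0212 kb and Wnt3 over 8.18 ± 0.0191 kb (SD, n = 2). Myf5, which initiates the skeletal muscle programme, had no peak within 5 kb in any list, and Myf6, Myog, Tbx6 and Msgn1 were the other unmarked members of its list. Prox1, unmarked in the replicated list, had peaks in both replicates (2.05 and 0.432 kb). Isx, Grhl3, Ehf and Trp63 were the remaining unmarked endoderm genes, and Fgf18, Bmp5 and Cer1 the unmarked signals. Members outside the naming rule are given where a count was 5 or fewer, and these were chosen after their values were seen.

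Within the heart's own regulators the mark divided the genes. All 30 genes of cardiac progenitors and regional patterning were marked (adjusted p = 8.70e-22, Fisher's exact test, two-sided), with Tbx1, a regulator of the outflow tract, covered over 9.77 ± 0.104 kb, Irx1 over 9.53 ± 0.286 kb and Six1 over 9.15 ± 0.176 kb (SD, n = 2). Of the 30, 16 also stood in another list. Of 29 cardiac transcription factors, 9 were marked (31.0%, Wilson 95% interval 17.3 to 49.2%), which missed the threshold against the other genes (adjusted p = 0.135, Fisher's exact test, two-sided). Gata4 had no replicated peak within 5 kb. The list passed the threshold on the pooled peaks (51.7%, adjusted p = 0.00970) and on the own peaks of replicate 1 (48.3%, adjusted p = 0.00727) and replicate 2 (44.8%, adjusted p = 0.0378), and over all 11 alternative settings, these included, adjusted p ran from 0.00727 to 1.0, all by the same exact test.

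The 9 marked cardiac factors included Nkx2-5, an early regulator of the heart (chromosome 17, 26838664 to 26845009, minus strand), with 7.35 kb of replicated peaks in its window of 10001 bp and 5.13 ± 0.222 kb in the replicates (SD, n = 2). Its strongest peak within 2 kb of a TSS spanned 26842592 to 26843322 inside an intron, with a signal value of 5.38. Irx4, a ventricular factor, had 6.51 kb and, within 2 kb of a TSS, a strongest peak at 73261045 to 73262836 on chromosome 13, also intronic. Esrrg had 5.80 kb, Prdm16 5.79 kb and Gata5 5.58 kb. Nfatc1, known for its role in valve formation, had 2.97 kb, Tbx5 2.83 kb, Hey1 1.36 kb and Heyl 0.628 kb. The replicates differed at the last 2 genes, with 0.611 and 1.78 kb at Hey1 and 1.26 and 0.579 kb at Heyl. The strongest Tbx5 peak within 2 kb of a TSS (chromosome 5, 119835287 to 119835903) lay in an intron, with a signal value of 3.10, below the median of 3.53 for all replicated peaks.

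**Figure D1:**
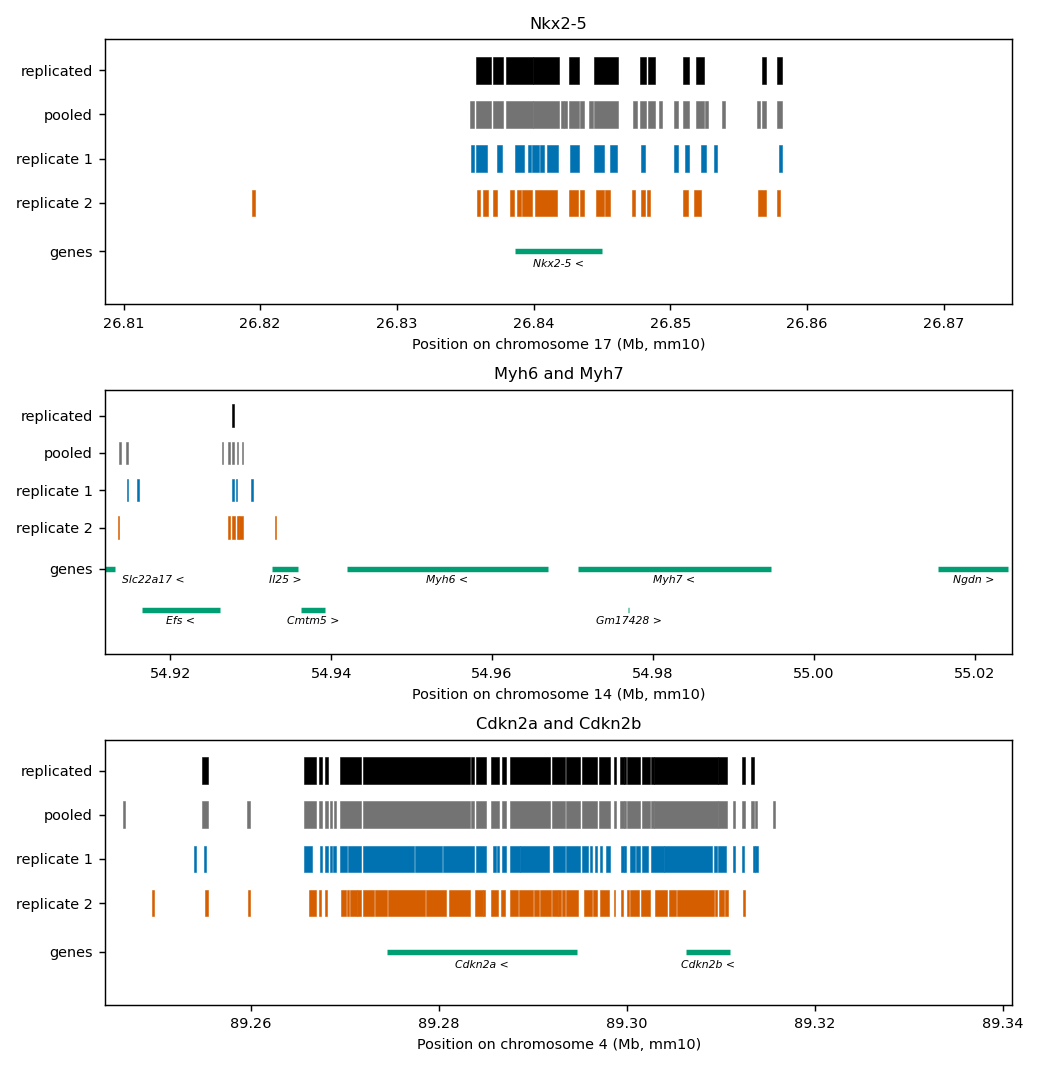
Peaks of the 4 lists (rows, black for replicated, grey for pooled, blue for replicate 1, orange for replicate 2) and protein-coding genes (green, > and < give the strand) at Nkx2-5, at Myh6 and Myh7, and at Cdkn2a and Cdkn2b; the horizontal axes give mm10 positions in Mb. Nkx2-5 and the pair Cdkn2a and Cdkn2b lie under peaks of all 4 lists, and the nearest replicated peak to a Myh6 TSS is 16590 bp away.

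Genes of the contractile apparatus were mostly free of the mark. Of 36 sarcomere genes 4 were marked (11.1%, Wilson 95% interval 4.41 to 25.3%), which missed the threshold against other genes (adjusted p = 0.334, Fisher's exact test, two-sided). These were Myl3, Nebl, Obscn and Tnni1, the slow skeletal troponin I of the fetal heart. Under replicated peaks they had 3.12, 2.79, 2.11 and 0.762 kb, in that order. Of the replicates, only replicate 1 had a peak at Tnni1 (0.462 kb). The strongest Myl3 peak within 2 kb of a TSS also lay in the overlapping gene Pth1r, so it may not belong to Myl3. Myh6 and Myh7, the cardiac myosin heavy chains (chromosome 14), had 0 bp covered within 5 kb in all 4 lists, and so had Nppa and Nppb, the natriuretic peptides. Tnni3, the cardiac troponin I, had 0.255 kb in replicate 2 and none in replicate 1 or the replicated list. Cardiac ion channel and calcium handling genes were marked more often, 16 of 36 (44.4%, adjusted p = 9.24e-04, Fisher's exact test, two-sided). Scn4b, a sodium channel subunit, had 7.43 ± 0.907 kb, Hcn4, the pacemaker channel, 4.54 ± 0.349 kb and Kcnd3 4.26 ± 0.199 kb (SD, n = 2), whereas Atp2a2, the calcium pump of the sarcoplasmic reticulum, had 0 bp. Against a background matched in GC content this list missed the threshold (adjusted p = 0.0547), and with the stronger part of the peaks by signal value its share was 25% (adjusted p = 0.124); over all 11 alternative settings, these included, adjusted p ran from 8.57e-04 to 0.124, all by the exact test.

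Among lists for other cell types of the heart, those of the epicardium, endothelium and smooth muscle stood above other genes, and that of fibroblasts was not called. Epicardial genes were marked in 11 of 16 cases (adjusted p = 5.39e-05, Fisher's exact test, two-sided), with Wt1 at 9.14 ± 0.185 kb and Bnc1 at 8.08 ± 0.182 kb (SD, n = 2). Upk3b, Upk1b, Aldh1a1, Msln and Scx were the unmarked ones. Endothelial genes were marked in 14 of 25 cases (adjusted p = 1.02e-04, Fisher's exact test). Examples were Tal1 at 8.23 ± 0.568 kb, Sox17 at 7.67 ± 0.277 kb and Sox7 at 7.08 ± 0.634 kb (SD, n = 2), whereas Pecam1 had 0 bp. Smooth muscle and pericyte genes reached 7 of 15 (adjusted p = 0.0220, Fisher's exact test). Among them were Pdgfrb with 3.51 ± 1.29 kb, Myh11 with 3.12 ± 0.590 kb and Mylk with 2.18 ± 0.248 kb (SD, n = 2), while the Acta2 peak lay 2234 bp from the TSS. That call was lost with replicate 1 alone (46.7%, adjusted p = 0.0773), against the background matched in GC content (adjusted p = 0.188) and when 25% of a window had to be covered (20.0%, adjusted p = 0.514); over all 11 alternative settings, these included, adjusted p ran from 0.00163 to 0.514, all by the exact test. Fibroblast genes were not called (8 of 24, adjusted p = 0.142, Fisher's exact test). Tcf21 stood at 7.04 ± 0.170 kb, Pdgfra at 7.31 ± 0.403 kb and Col1a1 at 4.49 ± 0.0438 kb (SD, n = 2), and Col3a1 had 0 bp. The fibroblast list passed on replicate 2's own peaks (50%, adjusted p = 0.0132) and on the pooled peaks (50%, adjusted p = 0.0305); over all 11 alternative settings, these included, adjusted p ran from 0.0132 to 0.161, all by the exact test.

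Among lists of other tissues, those of neuronal channels and synapses and of blood stood above other genes, and those of liver and germline were not called. Neuronal ion channel and synapse genes were marked in 33 of 40 cases (adjusted p = 2.20e-17, Fisher's exact test, two-sided), with the GABA synthesis enzymes Gad1 at 9.59 ± 0.0686 kb and Gad2 at 8.22 ± 0.689 kb and the vesicular transporter Slc32a1 at 9.31 ± 0.185 kb (SD, n = 2); Scn2a was unmarked. Blood and immune genes were marked in 13 of 35 cases (adjusted p = 0.0227, Fisher's exact test). They were led by the lymphocyte factors Pax5 at 9.59 ± 0.269 kb and Gata3 at 9.01 ± 0.283 kb and by Tal1 (SD, n = 2), and Ptprc, the pan-leukocyte antigen CD45, had 0 bp. This call was lost on the pooled peaks (42.9%, adjusted p = 0.0779), against the background matched in GC content (adjusted p = 0.0547), with the stronger part of the peaks (25.7%, adjusted p = 0.121) and when 25% of a window had to be covered (25.7%, adjusted p = 0.0678); over all 11 alternative settings, these included, adjusted p ran from 0.00394 to 0.121, all by the exact test. Liver genes were not called (3 of 20, adjusted p = 1.0, Fisher's exact test). The 3 were Apoa1 with 1.21 kb, Apob with 0.789 kb and Ahsg with 0.608 kb, and Alb, the gene of albumin, had 0 bp. Apoa1 was marked by neither replicate's own peaks. In replicates 1 and 2 Apob had 0.281 and 0.741 kb and Ahsg 0.623 and 0.807 kb. Germline genes were not called either (5 of 26, adjusted p = 1.0, Fisher's exact test), the 5 being Prm1, Prm2, Dppa3, Tdrd1 and Piwil1. The own peaks of replicate 1 marked 11 of the 26 and those of replicate 2 marked 7. Over all 11 alternative settings the share ran from 7.69 to 42.3%, and the lowest adjusted p was 0.0560, by the exact test. Prm1 and Prm2 are neighbours and shared 1 peak.

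Genes of energy metabolism and cell division stood below other genes. Of 51 oxidative phosphorylation genes 1 was marked, Atp5d (adjusted p = 0.00101, Fisher's exact test, two-sided). Its strongest peak within 2 kb of a TSS overlapped the neighbouring gene Cbarp and not Atp5d itself. By the same exact test none of 30 housekeeping genes (adjusted p = 0.00651) and none of 31 mitotic genes (adjusted p = 0.00430) had a replicated peak, counts of 0 that allow shares of up to 10% and 9.68%. Actb, Gapdh, Hprt and Tbp, and the mitotic regulators Cdk1, Ccna2, Ccnb1 and Ccnb2, had 0 bp within 5 kb in either replicate. Replicate 1's own peaks marked 2 housekeeping genes, Pgk1 on the X chromosome and Psmb4 on chromosome 3. Among 11 cell cycle inhibitors, 3 were marked (adjusted p = 0.489, Fisher's exact test, two-sided). Cdkn2a (chromosome 4, 89274471 to 89294653) had 8.15 ± 0.455 kb, its neighbour Cdkn2b 4.92 ± 0.460 kb and Cdkn1a 0.684 ± 0.462 kb (SD, n = 2), and Cdkn1b had 0 bp. The strongest Cdkn2a peak within 2 kb of a TSS spanned 89293501 to 89295004, 21.3% of it exonic and 55.4% intronic.

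Genes of Polycomb and Trithorax subunits, tested as 1 list, were marked in 9 of 33 cases (adjusted p = 0.318, Fisher's exact test, two-sided). Epop stood at 6.76 ± 0.0757 kb, Cbx8 at 5.78 ± 0.149 kb and Pcgf1 at 3.98 ± 0.436 kb (SD, n = 2), and Ezh1, a methyltransferase of H3K27, had 0 bp. Imprinted genes were marked in 10 of 29 cases (adjusted p = 0.0758, Fisher's exact test). Examples were Dio3 at 9.11 ± 0.0962 kb, Dlk1 at 7.75 ± 1.44 kb and Igf2 at 7.41 ± 0.321 kb (SD, n = 2), and Cdkn1c was unmarked in the replicated list. The imprinted list passed the threshold with a 1 kb window (34.5%, adjusted p = 0.0371), with replicate 2's own peaks (44.8%, adjusted p = 0.0378), at the 5′-most TSS (34.5%, adjusted p = 0.0310), with the stronger part of the peaks (31.0%, adjusted p = 0.0492) and when 25% of a window had to be covered (31.0%, adjusted p = 0.0238); over all 11 alternative settings, these included, adjusted p ran from 0.0238 to 0.917, all by the exact test. Of 23 lists, 12 were marked more often than other genes, 3 less often, and 8 were not called.

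**Figure D2:**
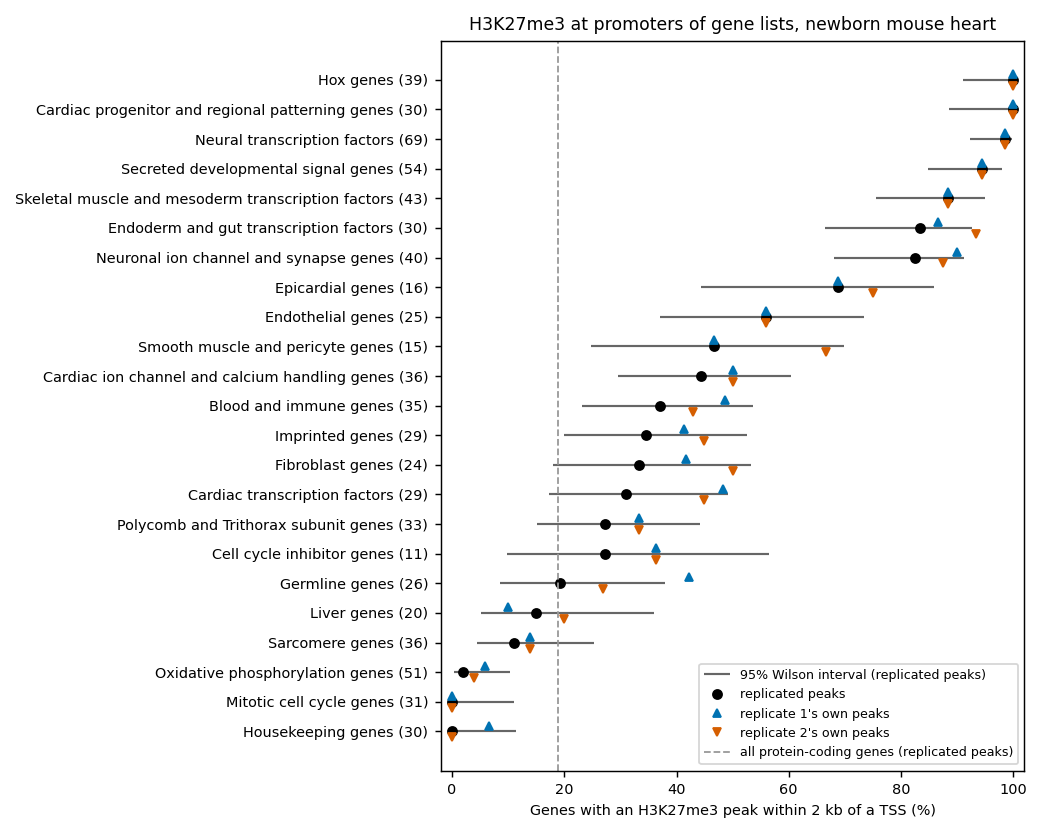
Share of genes in each of 23 lists (list size in parentheses) with a peak within 2 kb of a TSS, in percent on the horizontal axis. Black circles with bars give the replicated peaks and their Wilson 95% intervals, blue and orange triangles the own peaks of replicates 1 and 2, and the dashed line 18.9%, the share of all protein-coding genes; Hox genes and cardiac progenitor genes lie at 100% and mitotic genes at 0%.

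Gene families defined by symbol showed the same contrast. All 19 Wnt genes, 14 Nkx genes, 9 Pax genes, 8 Lhx genes, 6 Irx genes and 6 Dlx genes were marked (largest adjusted p of these 7.24e-05, Fisher's exact test, two-sided). By the exact test, potassium channels (Kcn) were marked in 67 of 92 cases (adjusted p = 3.25e-28), collagens in 26 of 44 (adjusted p = 1.28e-08), Fox factors in 29 of 44 (adjusted p = 4.90e-11), glutamate receptors in 20 of 24 (adjusted p = 6.07e-11) and cadherins in 11 of 23 (adjusted p = 0.00180). Keratins, the filament proteins of epithelia, were marked in 18 of 49 cases (adjusted p = 0.00326), and missed the threshold with a 1 kb window (26.5%, adjusted p = 0.128), with the stronger part of the peaks (22.4%, adjusted p = 0.154) and when 25% of a window had to be covered (20.4%, adjusted p = 0.206); over the 10 alternative settings for families adjusted p ran from 4.47e-09 to 0.206, all by the exact test. Of the Tbx family 9 of 13 were marked, with Tbx20, Tbx6, Tbx10 and Tbx19 unmarked. Of 6 Gata genes Gata2, Gata3 and Gata5 were marked and Gata1, Gata4 and Gata6 were not (adjusted p = 0.0891, and from 0.0395 to 0.157 over the alternative settings, Fisher's exact test, two-sided).

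Large receptor and zinc finger families stood below other genes. Olfactory receptors were marked in 10 of 1093 cases (0.915%, adjusted p = 7.83e-84, Fisher's exact test, two-sided) and vomeronasal receptors in 0 of 326, which allows a share of up to 0.920% (adjusted p = 2.45e-29). Zfp zinc finger genes reached 22 of 365 (6.03%, adjusted p = 8.30e-12, Fisher's exact test). Rpl3 was the single marked gene of 75 ribosomal proteins (adjusted p = 7.98e-06), Hist3h2ba of 100 clustered histone genes (adjusted p = 6.41e-08), and Pcdhac1 and Pcdhac2 the marked pair of 56 clustered protocadherins (adjusted p = 0.00183, all by the exact test). The own lists of replicates 1 and 2 marked 39 and 28 olfactory receptors, 1 and 0 vomeronasal receptors, and 36 and 36 Zfp genes. They marked 2 and 4 ribosomal protein genes, 3 and 3 histone genes, and 7 and 4 protocadherins. Of 30 families 21 stood higher, 7 lower, and 2 were not called. The family tests were not matched in GC or CpG content. Among all promoters, the lowest decile by observed over expected CpG was marked in 0.460% of cases and the second in 4.23%. Whether promoter CpG content accounts for the low shares of these families was not tested.

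In the replicated list the longest stretches of the mark lay over the Hox clusters and over a gene of the Groucho corepressor family. Replicated peaks joined across gaps of up to 3 kb formed 10252 domains, of which 185 held 20 kb or more of peak sequence. The most covered one lay on chromosome 9 from 61249856 to 61464050, with 178.4 kb under peaks. It contained Tle3 (61372366 to 61418497, plus strand), a transcriptional corepressor, and the non-coding genes B930092H01Rik, Gm10655 and Gm34322. The replicates' own peaks covered 145.7 and 158.5 kb of it, less than the 162.5 and 162.7 kb they covered of the HoxC domain. The HoxC cluster followed on chromosome 15 (102895088 to 103077275, 173.1 kb), then HoxB on chromosome 11 (96232178 to 96392092, 141.0 kb), HoxA on chromosome 6 (52143523 to 52281516, 132.1 kb) and HoxD on chromosome 2 (74642204 to 74770123, 120.9 kb). The widest single peak, 32071 bp on chromosome 11 from 96289334 to 96321404, ran across Hoxb4 to Hoxb7, with 24.5% of it exonic, 24.9% intronic and 50.6% intergenic.

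The next domains held Rhcg with the microRNA host Mir9-3hg, Sipa1l3, Pax7, Hoxb13 and Tbx3, a regulator of the cardiac conduction system (chromosome 5, 119619100 to 119693026, 62.2 kb). Domains at Cdh22, Kcnma1, Bin1 and Bmp10, a growth factor of the developing heart, also stood among the 20 most covered. Together these 20 contained the TSS of 57 protein-coding genes, and 3 of them contained none, their nearest protein-coding TSSs being those of Cadm1, Pax2 and Rhbg. Over gene bodies with 5 kb on either side, the gene with most covered sequence was Gm20388 on chromosome 8 (119910841 to 124345722, 250.5 kb), which had 0 bp of replicated peaks within 5 kb of its TSS, followed by Kcnma1, Sipa1l3, Sez6l, Cdh22, Pax7, Ltbp2, Gm28308, Hoxc5 and Lmx1b. The annotated Gm20388 runs across other genes, Foxf1 among them, and Gm28308 overlaps genes of the HoxA cluster. Their covered lengths therefore include peaks at those genes. When joining stopped at 1 kb, 10 of the 20 domains overlapped the 20 most covered.

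**Figure D3:**
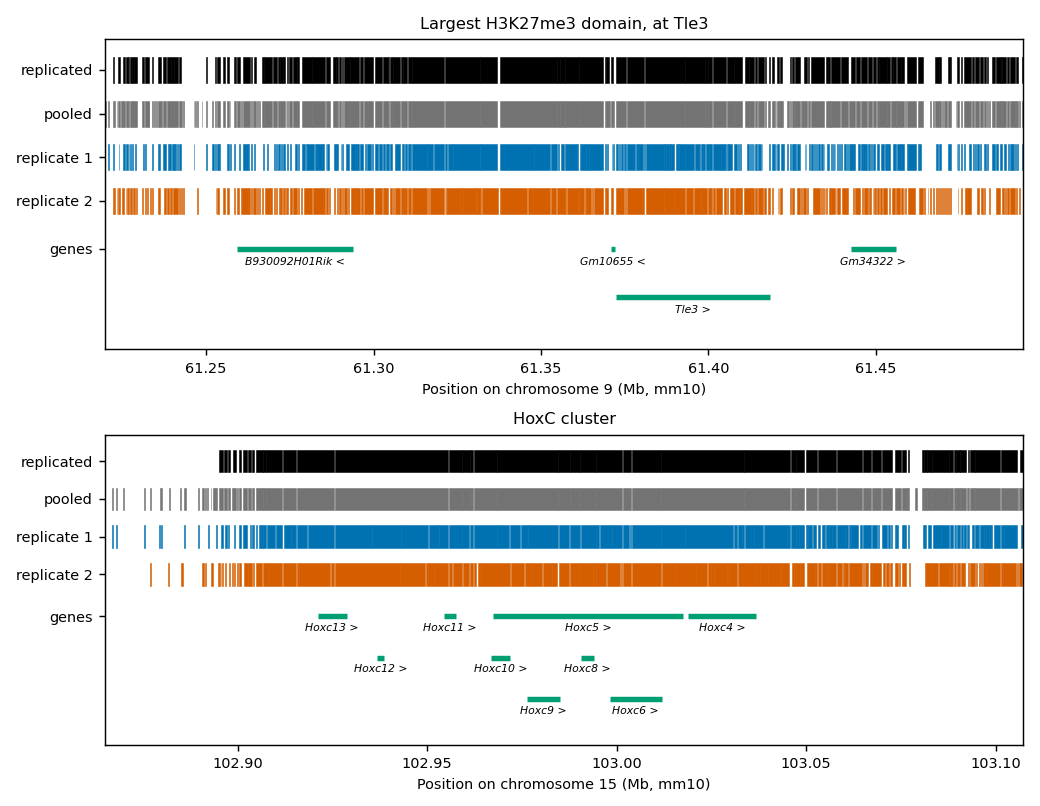
Peaks of the 4 lists and annotated genes (green, > and < give the strand) over the most covered domain at Tle3 on chromosome 9 and over the HoxC cluster on chromosome 15, with mm10 positions in Mb on the horizontal axes. Replicated peaks cover 178.4 kb of the first domain and 173.1 kb of the second.

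Promoters held more of the mark than their share of the genome. Windows of 2 kb around TSSs made up 6.68% of the genome and 36.6% of the base pairs under replicated peaks, 5.48 times as much. In 100 circular shifts of the peaks that share ran from 6.24 to 8.44%. Exons outside promoters held 4.67% against 2.25% of the genome, introns 22.3% against 31.8% and intergenic sequence 36.5% against 59.3%. In the replicates' own lists the promoter share was 32.3% for replicate 1 and 30.7% for replicate 2. Of the replicated peaks 8912 (32.0%) touched a promoter and 18947 did not. With a window of 1 kb the promoter share was 22.6%.

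The replicates shared their strong peaks and differed in their weak ones. Of replicate 1's peaks 46.2% overlapped a peak of replicate 2 by at least 1 bp, and 41.1% in the other direction, against at most 2.90% and 2.66% in 100 circular shifts. In the decile with the smallest p, 96.3% of replicate 1's and 95.2% of replicate 2's peaks were shared, and in the decile with the largest p 28.2% and 22.9%. Shared peaks of replicate 1 had a median width of 372 bp and a median signal value of 3.51, and unshared ones 226 bp and 3.05. The Jaccard index of covered base pairs was 0.348. Across 30637 overlapping pairs of peaks, Spearman's rho of the signal values was 0.364, a correlation across peaks, which are not independent replicates. The replicates' own peaks marked 5259 and 5477 promoters, 4365 of them in both. Each replicated peak had the same start and end as a pooled peak, and 78.6% of them overlapped peaks of both replicates.

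The X chromosome set the replicates apart. Replicate 1 had 4126 peaks on it and replicate 2 had 783, a ratio of 5.27, whereas on the 19 autosomes the ratio of replicate 1 to replicate 2 ran from 0.830 to 0.914 with a median of 0.889. Replicate 1 had 25.2 peaks per Mb on X, within its autosomal range of 14.6 to 41.8, and replicate 2 had 4.79, below its range of 16.0 to 47.1. The 1 Mb window with the most peaks in either replicate, 103 to 104 Mb, held 470 peaks in replicate 1 and 82 in replicate 2, and it contained Xist (103460366 to 103483254, minus strand), whose RNA coats the inactive X chromosome of females. Across the 172 windows of 1 Mb, Spearman's rho of the replicates' peak counts was 0.859, a correlation across windows. Of the 948 X-linked promoters, 109 were marked in replicate 1 only and 8 in replicate 2 only. Peaks on X overlapped replicate 2 for 11.3% of replicate 1's peaks, and on the autosomes for 48.5%. In the other direction 59.3% of replicate 2's peaks on X overlapped replicate 1, and 40.9% of those on the autosomes. The low share for replicate 1 thus goes with the shorter X list of replicate 2. Without X, 4027 of 20780 promoters were marked, and 12 lists again stood higher and 3 lower.

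**Figure D4:**
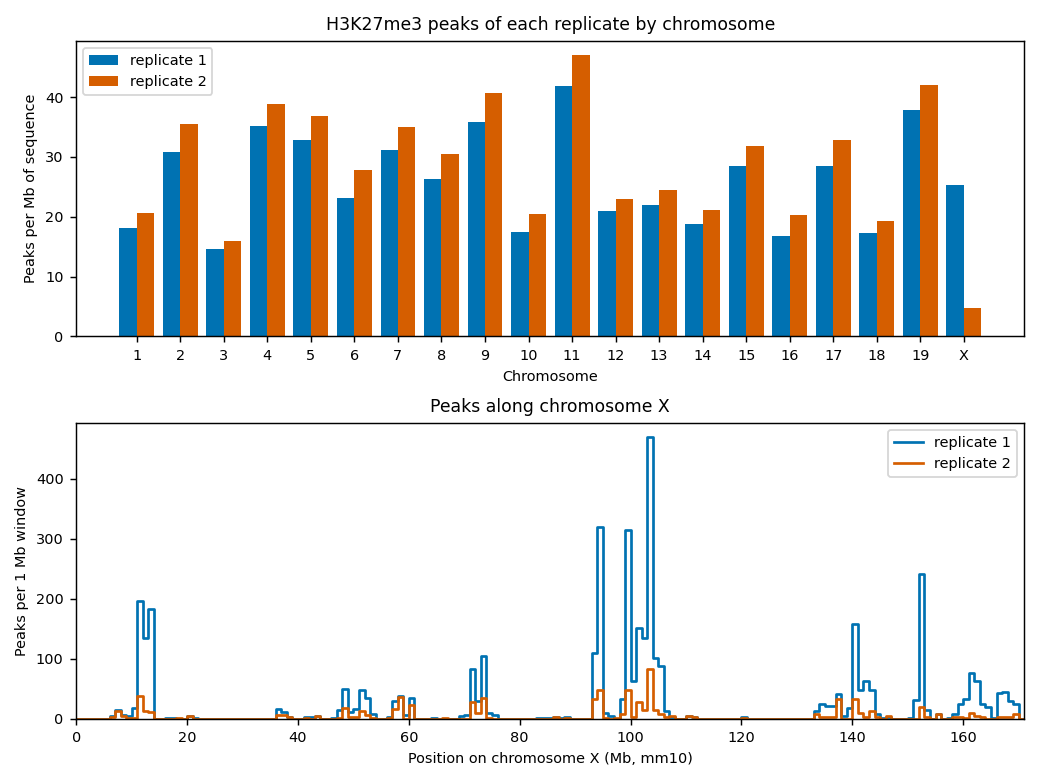
Top, bars from 0 give peaks per Mb of sequence on each chromosome for replicate 1 (blue) and replicate 2 (orange). Bottom, peaks per 1 Mb window along X (mm10, Mb); replicate 1 reaches 470 and replicate 2 reaches 82 in the window that contains Xist.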

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

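The test of depth was chosen only after the X chromosome result was seen; the other tests given here were chosen before their results were seen.

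On the X chromosome 3387 peaks of replicate 1 lay outside both replicate 2's peaks and the replicated list, a signal in data that the main comparisons of gene lists, made on the replicated list, did not use. Of all X peaks of replicate 1, 3660 (88.7%) had no counterpart in replicate 2, which had only 783 peaks on X. The unshared X peaks had a median width of 234 bp, and unshared autosomal peaks of replicate 1 had 225 bp.

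The excess on X was weighed against 3 explanations. Deeper sequencing or a looser peak limit in replicate 1 would raise the autosomes too, and their median ratio of 0.889 argues against it. A control of replicate 1 with too few X reads (or one of replicate 2 with too many) would raise the signal values of shared X peaks, and these were higher in replicate 1 by 0.18 on the log2 scale relative to autosomes (bootstrap interval 0.12 to 0.23, 466 shared peaks), which lies below the 0.5 expected and argues against a control deficit of that size, but the interval passes the 0.2 set as the bound against this explanation and shared peaks are not the peaks in excess, so a smaller deficit stays open. A larger share of cells with an inactive X in replicate 1 may also account for it. The pooling of males and females allows this biological explanation. In replicate 1, 6 of 40 X-linked housekeeping promoters (15.0%) were marked, and 0 in replicate 2. Any cause of the excess, which is relative to replicate 2, would give this direction. In replicate 1, 22.2% of all X promoters were marked, against 24.3% of autosomal ones. In replicate 2 these shares were 11.5% and 25.8%. Of 108 autosomal housekeeping, oxidative phosphorylation and mitotic genes, replicate 1 marked 4 (3.70%) and replicate 2 marked 2 (1.85%). Of 10 genes listed as escaping inactivation, with Xist itself among them, 3 were marked in replicate 1 (Mid1, Xist and Ftx). In replicate 2, 2 were marked (Mid1 and Kdm6a). Mid1 was thus marked in both replicates, and Xist and Ftx had 190 and 251 bp within 5 kb in replicate 1. That escape genes were marked at a higher share than housekeeping genes in replicate 1 rests on these short stretches. In replicate 1 the comparison of housekeeping with escape genes did not separate the lists (p = 0.358, Fisher's exact test, two-sided). With 6 of 40 housekeeping promoters marked, 10 escape genes were too few for a lower share among them to pass the threshold. This holds even had no escape gene been marked, so the comparison cannot decide this question and no conclusion is drawn from it. The control and the inactive X cannot be told apart here, since the number of females in each pool and the control reads are not given in the sources used here.

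Promoters of 471 lincRNA genes had a replicated peak (784 and 838 had one in the replicates' own lists), in a gene class that the comparisons of protein-coding genes left out.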

How the results depend on the processing

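Leaving out the X chromosome was chosen only after the data were seen; the other settings were chosen before. The number of marked promoters, 4113, lay between 2965 and 6033 in all settings run, and between 14 and 18 of the 23 lists were called, except with the background matched in GC content, which called 12. The share of marked genes in a list is given below with its list; the cause of each change was not tested. No paired analysis was possible because the series has 1 group. Leaving out a replicate leaves no overlap to measure. Depth is unknown, so it cannot be said which weak peaks more reads would add.

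The share among other genes changes with the setting, so list shares cannot all be set against 18.9%. For cardiac transcription factors it was 27.7% on the pooled peaks, 25.2% without replicate 1 and 24.2% without replicate 2. It was 14.75% with the stronger part of the peaks and 13.6% with 25% of a window covered. On the pooled peaks cardiac transcription factors (51.7%) and fibroblast genes (50%) became called, blood and immune genes (42.9%) lost their call, and liver genes (30%) turned from below to above other genes without a call. Leaving out a replicate gave 44.8 to 48.3% for cardiac transcription factors (called both times), 41.7 to 50% for fibroblast genes and 41.4 to 44.8% for imprinted genes (both called only without replicate 1), and 46.7 to 66.7% for smooth muscle genes (not called without replicate 2). With a GC-matched background the calls of ion channel (44.4%), smooth muscle (46.7%) and blood and immune genes (37.1%) were lost. In that setting uncalled lists changed side, cardiac transcription factors (31.0%) and Polycomb and Trithorax subunit genes (27.3%) to lower and liver genes (15%) to higher. With the stronger part of the peaks by signal value, ion channel genes (25%) and blood and immune genes (25.7%) lost their call and imprinted genes (31.0%) gained one. With 25% of a window covered, smooth muscle genes (20%) and blood and immune genes (25.7%) lost it and imprinted genes (31.0%) gained it, as they did with the 1 kb window and the 5′-most TSS (34.5% each). Germline genes, uncalled throughout, fell below other genes at 1 kb (15.4%), at 5 kb (19.2%), with the stronger peaks (11.5%), with 25% covered (7.69%) and at the 5′-most TSS (11.5%). Their share was 34.6% on the pooled peaks, 26.9% without replicate 1 and 42.3% without replicate 2 (adjusted p = 0.0560, Fisher's exact test).

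The overlap of replicate 1's peaks was 35.6% and of replicate 2's 29.8% when 50% of a peak had to be covered, 54.1% and 49.4% at −log10 p of at least 5 (Jaccard index 0.448), 44.9% and 42.5% for equal numbers of top peaks, and 34.1% and 30.2% with peaks joined up to 1 kb (Jaccard index 0.435). Without X it was 48.5% for replicate 1. The promoter share of covered sequence was 28.5% for pooled peaks, 30.7 to 32.3% without a replicate and 22.6% with the 1 kb window, and the intergenic share 41.8%, 40.03 to 40.4% and 40.9%. Joining up to 1 kb left 10 of the 20 largest domains overlapping. Covered lengths of named genes under other peak lists and limits moved by more than the replicates' SD in 243 comparisons and stayed within it in 482. Named genes with 0 bp in every list could only stay, and the limit on −log10 q kept 96.99% of replicated peaks. The 482 is therefore no measure of how stable the lengths are. The background matched in GC content was not run for families. Over the other settings 5 tests of single families gained a call (Gata and proteasome genes), 3 lost one (all keratins) and the others kept direction and side of the threshold.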

Other observations

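The tests of non-coding genes and of CpG content were chosen only after the peaks were seen; the test of the cardiac factors was chosen before its result was seen.

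Of lincRNA genes 10 kb or more from a protein-coding TSS, 271 of 4291 (6.32%, Wilson 95% interval 5.63 to 7.08%) were marked, and of those nearer than 10 kb 200 of 1014 (19.7%, interval 17.4 to 22.3%). The distant lincRNA genes with most covered sequence were Gm11535, Gm3764 and AI849053, and the first 10 also held Mir9-3hg on chromosome 7 (79500026 to 79534403), with 9.84 kb of its window of 10001 bp under replicated peaks, Mir124a-1hg on chromosome 14 with 9.72 kb and Mir124-2hg on chromosome 3 with 9.63 kb, which host miR-9 and miR-124, microRNAs of the nervous system. C130071C03Rik on chromosome 13 had 9.86 kb. Both replicates covered these genes, Mir9-3hg over 9.65 and 9.76 kb and Mir124-2hg over 9.23 and 8.94 kb. Several lay inside domains given above and are not separate from them. Gm11535 lay in the Hoxb13 domain, Gm3764 and AI849053 in the domain nearest Rhbg, and Mir9-3hg in the Rhcg domain. By the annotated gene start alone, 8.88% of lincRNA genes, 13.9% of antisense genes and 7.51% of microRNA genes were marked, against 16.9% of protein-coding genes.

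By the authors' signal value the first peaks of the replicated list lay at Kcnc1 on chromosome 7 (46393350 to 46400182, signal 14.1), Nrxn2 on chromosome 19 (6425443 to 6431751, 84.6% intronic), Pcdh8 on chromosome 14, Slc12a5 on chromosome 2 and Grik3 on chromosome 4, followed by peaks at Gsx1, Hmx1 and Egr4, one on chromosome 9 that overlapped no protein-coding gene, and one at Wnt9b. These genes were picked from the ranked peaks after their values were seen.

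In the lowest decile of promoters by observed over expected CpG, 10 of 2173 were marked (0.460%), in the second 4.23%, in the fifth 26.97% and in the highest 22.9%. The replicates gave 2.76% and 2.30% in the lowest decile, 9.99% and 11.2% in the second and 33.0% and 34.4% in the fifth.

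Whether the marked cardiac transcription factors owe their call to peaks that touch only the edge of the promoter window was tested by asking for 25% of a window. Of the 9 genes, 8 stayed marked and Heyl did not, which argues against edge contact as the source of most of these calls.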
